A study of Mus musculus with 4 samples.

How the data were processed

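The series holds RNA sequencing of mammary cells from 5-week-old female mice with a fluorescent reporter at the Lgr6 locus, sorted into Lgr6-positive and Lgr6-negative populations, with 2 libraries each. Glands were digested enzymatically and red cells were lysed before a sort from lineage-negative cells, of which the markers and the Lgr6-negative gate are not given in the sources used here. The labels state RNA of 7 to 25 pg per µl with integrity numbers of 5 to 8, 18 PCR cycles and paired reads of 50 bases. The authors deposited 1 table of expected counts per gene (estimated by RSEM, not scaled for depth) for 24442 genes in the 4 libraries. RSEM 1.2.22 and STAR 2.4.2a, with the genome build mm10, are named per the submitters' processing notes. The annotation, strand setting and read trimming are not given in the sources used here. Between 3.36% and 4.86% of the genes in a library had a fractional value, and values were rounded to whole counts. Total counts were 6819127 and 6995568 in the Lgr6-positive and 6920996 and 7167465 in the Lgr6-negative libraries, with 14144, 11959, 12378 and 12048 genes detected. A floor of 3 counts corresponds to 0.368, 0.380, 0.468 and 0.533 CPM (counts scaled to a common library size) after normalization. The table held no mitochondrially encoded genes.

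Groups and replicate numbers were taken from the sample labels, which do not say whether the replicates came from separate animals. Replicates were checked for identical values and for differences beyond counting noise, with a chi-square per degree of freedom of 100.9 in the Lgr6-positive and 86.4 in the Lgr6-negative pair. Counts were analysed with edgeR 4.0.16 in R 4.3.3, with TMM factors of 1.21, 1.13, 0.929 and 0.787. The filterByExpr function (minimum count 10, minimum total 15) kept 11661 genes. The test was glmQLFit and glmQLFTest with group as the only factor and a Benjamini-Hochberg adjusted p under 0.05. The common dispersion was 0.795. Log2 fold changes are Lgr6-positive over Lgr6-negative, and their standard errors (SE) are the absolute log2 fold change over the square root of F. Means and SD are of TMM-normalized CPM. For a gene without counts in both libraries of a population, the fold is a bound against 3 counts per library, and for 1 to 3 counts it is a ratio with a 95% counting interval.

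Genes named in the text were chosen by a rule fixed before the data were examined. It took Lgr6, Lgr4 and Lgr5, then the 10 genes with the smallest p-values in each direction among those past the threshold with libraries that do not overlap. From each list it added up to 4 tested members with the smallest p-values. Ribosomal protein genes, mitochondrially encoded genes and gene models known by clone or model number were passed over and counted. The rule gave 93 genes, and others are named as chosen after their values were seen.

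Before the data were examined, 20 lists with 306 genes were fixed. They cover basal, pan-luminal, hormone-sensing luminal and secretory or progenitor luminal cells, fibroblasts, adipocytes, endothelium, pericytes, leukocytes, red cells, Schwann cells, keratinocytes, skeletal muscle, the Wnt and Notch pathways, proposed stem cell markers, proliferation, immediate early and stress genes, basement membrane, and EGF receptors with their ligands. Of these genes, 252 were tested, and Flg and Ahsp were not analysed here. Lists with at least 3 tested genes were tested with camera in limma 3.58.1 (preset correlation 0.01, log2 CPM with prior count 2), with camera under an estimated correlation and with fry. A further 12 lists were written after values were seen: monocytes, macrophages, neutrophils, conventional and plasmacytoid dendritic cells, B, T, natural killer and mast cells, fatty acid synthesis, milk fat globule and uptake, and red-cell genes other than globins.

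Gene positions, lengths and GC content came from GENCODE M21 (GRCm38, the build also called mm10), matched by symbol for 11274 of 11661 tested genes (96.7%) and 91 of the 93 named genes. Hbb-b1 and Hbb-b2 were not matched. Alternatives to the scaling, filter, test, design and libraries are given in the closing section, with DESeq2 1.42.0 and limma-voom as other tests. Other computations used Python 3.11.15 with scipy 1.17.1, numpy 2.4.6 and pandas 2.3.3. Bootstrap intervals used 10000 resamples.

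The steps were tested on simulated data with 2 libraries per group and known changes. Of genes changed 16-fold, 19 of 66 were called (28.8%), of those changed 4-fold, 1 of 67, and of those changed 2-fold, 0 of 67. There were 5 unchanged genes among the calls (20.0% of them), a larger share than the adjusted p threshold allows for. This was a single run with few changed genes, so the share does not carry over to the real data. Of the unchanged lists, 0 of 20 were called. That result covers the simulated lists only. It is no check on correlation between genes in the real lists, so it does not limit false list calls there.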

Results

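RNA was measured by sequencing in cells sorted by flow cytometry from the mammary glands of 5-week-old female mice that carry a green fluorescent reporter and an inducible recombinase at the Lgr6 locus. The cells were collected as an Lgr6-positive and an Lgr6-negative population, with 2 libraries of each and 4 libraries in all. The labels describe a sort from lineage-negative cells but give neither the lineage markers nor the gate of the Lgr6-negative population. The libraries were of similar depth, with 6819127 and 6995568 counts in the Lgr6-positive and 6920996 and 7167465 counts in the Lgr6-negative population. Between 11959 and 14144 of the 24442 genes in the table had at least 1 count in a library. The 45S ribosomal RNA precursor Rn45s took 17.2% and 14.5% of the counts of the Lgr6-positive libraries and 18.7% and 30.8% of those of the Lgr6-negative libraries. Across genes, which are not independent replicates, log2 CPM (counts scaled to a common library size) correlated at 0.703 between the Lgr6-positive libraries, at 0.783 between the Lgr6-negative libraries and at 0.380 to 0.447 between libraries of different populations. The labels do not say whether the replicates came from separate animals, so the p-values measure only the spread between these samples, which may be technical.

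The comparison asked which genes distinguish Lgr6-positive from Lgr6-negative mammary cells. Lgr6-positive libraries carried epithelial keratins, hormone-receptor and milk-protein genes, together with haemoglobin genes and some endothelial, fibroblast and keratinocyte genes, at higher levels. Lgr6-negative libraries carried genes of leukocytes, among them lysozyme and class II antigen presentation genes. Of 11661 tested genes, 524 were higher and 533 lower in Lgr6-positive cells in edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05. In a single simulated run of the same steps, 5 unchanged genes made up 20% of the calls. Far fewer genes were changed there than were called here, so that share does not carry over. The false share here is not known and may exceed the threshold. Differences that passed were large, with a median absolute log2 fold change of 4.68 and a smallest of 0.83. That median includes fitted values of genes without counts in 1 population, which are not bounds. Of simulated genes, 0 of 67 changed 2-fold, 1 of 67 changed 4-fold and 19 of 66 changed 16-fold were called. The test thus favours large differences, and genes that did not pass, here and below, may still differ. Of the higher genes, 114 had no counts in both Lgr6-negative libraries, and 63 of the lower genes had none in both Lgr6-positive libraries. Without replicate 1 of the Lgr6-positive population, 956 genes were higher and 1030 lower, and these held 1014 of the 1057 reported. Scaling by library size alone shifted all log2 fold changes by a median of 0.45 and made 65.8% of the calls higher, against 49.6% as reported, and DESeq2 made 60.4% higher.

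Lgr6, the leucine-rich repeat receptor gene whose locus carries the reporter, had 172 and 655 counts in the Lgr6-positive libraries. It had 3 and 10 counts in the Lgr6-negative libraries. This gave 52.0 ± 43.8 CPM against 1.12 ± 0.93 CPM (mean ± SD, n = 2 libraries each, as for all CPM values) and a log2 fold change of 5.52 (SE 1.47). Every Lgr6-positive library lay above every Lgr6-negative library, but the adjusted p of 0.0510 missed the threshold. Over the alternative settings its adjusted p ran from 7.48e-05 to 0.349, the highest without replicate 2 of the Lgr6-positive population and with a log2 fold change of 4.19. It passed without replicate 1 of that population (adjusted p = 0.00232) and without replicate 2 of the Lgr6-negative population (0.0271), and in all under 8 of 14 alternatives. The gene lies on chromosome 1 of GRCm38 from 134983301 to 135105276, on the minus strand. Lgr4, a related receptor for R-spondins on chromosome 2 from 109917647 to 110014257, was higher at 86.4 ± 54.3 against 6.14 ± 1.62 CPM (log2 fold change 3.81, SE 0.99, adjusted p = 0.0472). That call was lost without replicate 2 of the Lgr6-positive population (adjusted p = 0.294), without replicate 1 (0.0745) or replicate 2 (0.0505) of the Lgr6-negative population, under a stricter filter (0.05003) and in limma-voom (0.136), within a range of 3.08e-04 to 0.294. Lgr5, on chromosome 10 from 115450311 to 115587780, had 19 and 123 counts in the Lgr6-positive and 163 and 4 in the Lgr6-negative libraries. Its log2 fold change of -0.55 (SE 1.90, adjusted p = 0.915) changed sign when single libraries were left out, reaching 3.62 without replicate 1 of the Lgr6-negative population.

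The leading gene among those higher in Lgr6-positive cells was Prlr, the prolactin receptor, at 1319.9 ± 39.0 CPM against 8.65 ± 0.09 CPM (log2 fold change 7.25, SE 0.39, adjusted p = 8.24e-05). It spans bases 10177238 to 10349180 of chromosome 15. Insulin-like growth factor binding protein Igfbp5 (log2 fold change 4.25, SE 0.28), the plasma glutathione peroxidase Gpx3 (6.58, SE 0.55), the stearoyl-CoA desaturase Scd1 (3.94, SE 0.34) and the surface protein Plet1 (4.76, SE 0.43) followed. So did the epithelial keratins Krt19 (5.09, SE 0.41), Krt18 (4.60, SE 0.40) and Krt14 (4.59, SE 0.42). Exons of other genes cover 13.4% of the exonic bases of Plet1, so part of its counts may belong to a neighbour. Dmbt1, a secreted scavenger-receptor glycoprotein on chromosome 7 from 131032053 to 131121630, reached 501 ± 39.1 CPM and Btn1a1, the butyrophilin of milk fat globules, 409 ± 157 CPM. Both had no counts in the Lgr6-negative libraries, and against a floor of 3 counts per library they were at least 1001-fold and at least 817-fold higher. Adjusted p-values of these 10 genes ran from 8.24e-05 to 6.85e-04. A further 7 higher and 25 lower genes were ribosomal protein genes or gene models without a symbol of their own and are not named.

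Genes lower in Lgr6-positive cells were led by the lysozyme gene Lyz2, at 1205 ± 233 CPM against 17669 ± 986 CPM (log2 fold change -3.87, SE 0.20, adjusted p = 8.24e-05). Lyz2 spans bases 117277331 to 117282321 of chromosome 10. Il1b, the interleukin-1 beta gene on chromosome 2 from 129364570 to 129371139, fell by 5.71 on the log2 scale (SE 0.30), from 2950.4 ± 25.9 CPM in Lgr6-negative to 56.5 ± 5.83 CPM in Lgr6-positive cells. The myeloid transcription factor gene Spi1 (-7.14, SE 0.53), the platelet and leukocyte protein gene Plek (-5.79, SE 0.45), the class II invariant chain gene Cd74 (-3.74, SE 0.29) and the ferritin heavy chain gene Fth1 (-2.81, SE 0.22) were also lower. Ms4a6b, Trem1 and Treml4, which encode leukocyte surface proteins, had no counts in the Lgr6-positive libraries and were at least 1000.05-fold, at least 1025-fold and at least 895-fold lower. Jchain, which encodes the joining chain of polymeric immunoglobulins, had 1 count in the Lgr6-positive libraries against 4837 and 5098, a ratio of 13247 with a 95% counting interval from 2377 to 523280.3. Such intervals and floors cover counting error only, since amplified reads without molecular identifiers are not independent molecules. Adjusted p-values of these 10 genes ran from 8.24e-05 to 4.81e-04.

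**Figure D1:**
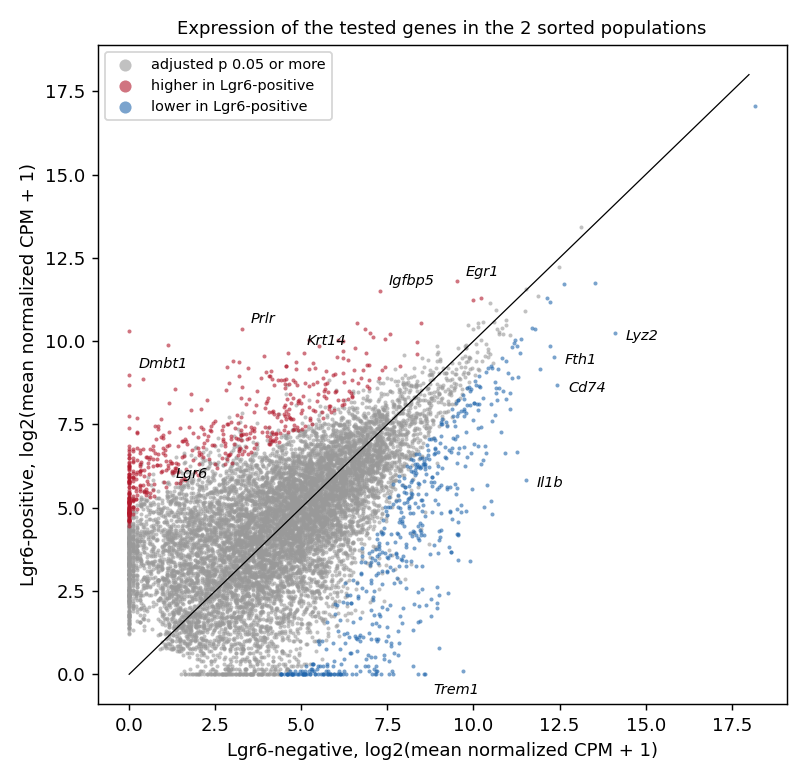
Mean expression of each tested gene in the Lgr6-negative (x axis) and Lgr6-positive (y axis) libraries, as log2 of normalized CPM plus 1, with n = 2 libraries per population and the line of equality in black. The 524 genes higher in Lgr6-positive cells are red and the 533 lower genes are blue, with Lyz2 at 17669 CPM in Lgr6-negative against 1205 CPM in Lgr6-positive libraries.

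Of 18 tested members of the immune list, 13 were lower, none was higher and 5 did not pass, with 15 lower when adjusted over the list alone and a median log2 fold change of -3.87. Ptprc, the pan-leukocyte marker CD45, was at 35.9 ± 17.6 CPM against 1466 ± 391 CPM (log2 fold change -5.35, SE 0.48, adjusted p = 5.80e-04). H2-Aa, a class II histocompatibility gene, fell by 3.12 on the log2 scale (SE 0.30), beside Lyz2 and Cd74. The list ranked below other genes in camera (adjusted p = 6.53e-10, and 0.127 with an estimated correlation). Its median stayed at -3.42 under library-size scaling. In the same libraries Rn45s was lower in Lgr6-positive cells (log2 fold change -1.13, SE 0.24, adjusted p = 0.0225), a call lost under library-size scaling (0.0871) and in DESeq2 (0.237). Its adjusted p was as low as 2.65e-70 over the other alternatives, and its log2 fold change was -0.58 without replicate 2 of the Lgr6-negative population. Actb (-1.77, SE 0.17) and B2m (-2.36, SE 0.21), chosen after their values were seen, were also lower in Lgr6-positive cells, under each scaling.

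Genes of both epithelial layers of the mammary gland were among those higher in Lgr6-positive cells, in which the immune list had a median of -3.87. In the basal list, 6 of 20 tested genes were higher and 14 did not pass, all 14 with positive fold changes, and 11 were higher when adjusted over the list alone (camera adjusted p = 1.24e-05, and 0.127 with an estimated correlation). Besides Krt14, they included the basal keratin Krt5 at 649.8 ± 75.9 against 39.7 ± 27.5 CPM (log2 fold change 4.03, SE 0.57) and the basal transcription factor Trp63 (3.95, SE 0.71). The hemidesmosome integrin Itgb4 (4.31, SE 0.82, adjusted p = 0.0139) lost its call in limma-voom (0.0505, in a range from 1.84e-06). Of 15 pan-luminal genes, 11 were higher, 4 did not pass and 13 were higher when adjusted over the list alone (camera adjusted p = 2.53e-08, and 0.127 with an estimated correlation). Epcam rose to 546 ± 2.399 from 16.3 ± 5.91 CPM (log2 fold change 5.07, SE 0.50) and the epithelial cadherin Cdh1 by 4.37 on the log2 scale (SE 0.44), beside Krt18 and Krt19.

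Hormone-sensing luminal genes had the highest median log2 fold change of the epithelial lists, 6.02. Of 14 tested, 10 were higher, 4 did not pass and 12 were higher when adjusted over the list alone (camera adjusted p = 2.58e-08, and 0.143 with an estimated correlation). Pgr, the progesterone receptor, was at 164 ± 48.7 against 0.778 ± 0.659 CPM (log2 fold change 7.70, SE 0.99, adjusted p = 0.00257). Next to Prlr, Prom2 was at 6.65 (SE 0.98, with 5.83 to 8.57 over the alternatives) and the growth factor receptor gene Fgfr2 at 7.97 (SE 1.27). All 17 counts of Fgfr2 in Lgr6-negative cells came from replicate 2, so without that library no ratio can be given for it. In the list of luminal secretory and progenitor genes, 10 of 14 were higher, 1 was lower and 3 did not pass, with 12 higher and 1 lower when adjusted over the list alone (camera adjusted p = 1.47e-05, and 0.127 with an estimated correlation). Glycam1, which encodes a milk mucin, had no counts in the Lgr6-negative libraries and was at least 427-fold higher, and the kappa-casein gene Csn3 rose to 1038 ± 14.3 from 36.2 ± 29.8 CPM (log2 fold change 4.84, SE 0.63). Trf, the transferrin gene (3.04, SE 0.34), shares 63.5% of its exonic bases with other annotated genes, so its counts may be mixed, while Wfdc18 (3.06, SE 0.44) shares none. The lower member was Cd14 (-2.51), named after its value was seen, which encodes a lipopolysaccharide co-receptor that myeloid cells also make. Over the same libraries the immune list had a median of -3.87.

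**Figure D2:**
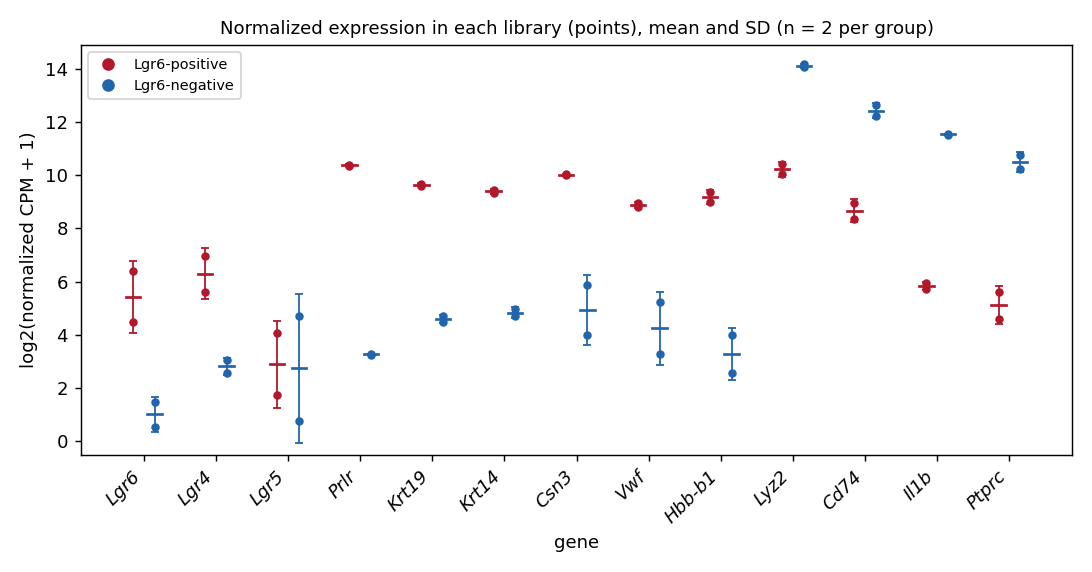
Expression of 13 genes in each library as log2 of normalized CPM plus 1, with points for libraries, bars for the mean and whiskers for the SD (n = 2 per population). Lgr6 had a wide spread in Lgr6-positive libraries, at 52.0 ± 43.8 CPM, whereas Prlr was at 1319.9 ± 39.0 CPM and Lyz2 was higher in both Lgr6-negative libraries.

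Of 13 endothelial genes, 5 were higher and 8 did not pass, with 7 higher when adjusted over the list alone (camera adjusted p = 1.86e-04, and 0.127 with an estimated correlation). Vwf, the von Willebrand factor gene, reached 467 ± 37.6 against 22.5 ± 19.5 CPM (log2 fold change 4.37, SE 0.70), followed by Eng (3.80, SE 0.61), the vascular cadherin gene Cdh5 (3.39, SE 0.55) and Pecam1 (2.51, SE 0.44). The fifth, Kdr (3.87, adjusted p = 0.0352), was named after its value was seen and did not pass without replicate 2 of the Lgr6-positive population (0.0516) or in limma-voom (0.0859, in a range from 5.85e-05). Among 16 fibroblast genes, 6 were higher and 10 did not pass, with 10 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.00169, and 0.199 with an estimated correlation, or 0.0554 under a stricter filter). Fbn1, the fibrillin gene, was at 169 ± 8.95 against 10.55 ± 1.68 CPM (log2 fold change 4.002, SE 0.66), though 20.1% of its exonic bases lie in other genes. Col1a2 was higher by 3.85 (SE 0.76), and Col6a2 and Pdgfra, with no counts in Lgr6-negative libraries, were at least 96.1-fold and at least 107-fold higher. These bounds fell to 50.6-fold for Col6a2 without replicate 1 and 23.8-fold for Pdgfra without replicate 2 of the Lgr6-positive population. Without the latter library, Pdgfra lost its call (adjusted p = 0.149, the highest in a range from 1.31e-06). These lists moved opposite to the immune list, at a median of -3.87.

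Of 7 pericyte genes, only Rgs5 was higher, with 1 count in Lgr6-negative against 259 and 323 in Lgr6-positive libraries, a ratio of 436 with a 95% counting interval from 78.0 to 17269.7. The other 6 did not pass, among them Abcc9 (log2 fold change 4.53, adjusted p = 0.219) and Mcam (3.89, 0.249), and 2 were higher when adjusted over the list alone. The pericyte list passed camera (adjusted p = 0.00550, and 0.420 with an estimated correlation), but neither fry (0.149) nor camera without replicate 1 of the Lgr6-positive population (0.0967). Abcc9 passed without replicate 2 of the Lgr6-positive population (5.36, 0.0149) and without replicate 2 of the Lgr6-negative population (0.0219), which held all 17 of its Lgr6-negative counts, and was at 2.17 without replicate 1 of the Lgr6-positive population. The adjusted p of Abcc9 ran up to 0.698, and Mcam passed in DESeq2 (0.0429, in a range up to 0.615). Of 4 tested adipocyte genes, Lpl, the lipoprotein lipase gene, was higher (4.02, SE 0.47, adjusted p = 0.00175), and 1 was higher when adjusted over the list alone. Fabp4 (1.98, adjusted p = 0.157), Pparg (-2.33, 0.608) and Plin4 (-2.15, 0.651) did not pass. Below the filter, some list members had counts in Lgr6-positive libraries alone, nearly all from a single library per gene. These were Car3 (516 and 1 counts), Plin1 (0 and 123), Adig (50 and 0), Cfd (34 and 0) and Adipoq (18 and 1). Cidec, Lep and Retn had no counts in any library. The list's median of -0.09 and its mean of 0.38 differed in sign, and camera gave an adjusted p of 0.646 (0.735 with an estimated correlation), or 0.0111 without replicate 2 of the Lgr6-positive population in a range up to 0.840. Without replicate 1 of that population, which left no counts of Pparg or Plin4 there, Pparg was lower (adjusted p = 0.0464, in a range up to 0.995). Pparg was at -0.10 without replicate 2 of the Lgr6-negative population and Plin4 at -1.02 without replicate 1. The median of the list depended on the libraries, at 1.78 and 5.43 without replicate 1 or 2 of the Lgr6-positive and 6.08 and 6.13 without replicate 1 or 2 of the Lgr6-negative population, against 0.38 under library-size scaling. These fits tested 5 to 9 genes and their medians include fitted values of genes without counts in 1 population, so they are not bounds.

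Of 7 tested keratinocyte genes, 3 were higher, 4 did not pass and 6 were higher when adjusted over the list alone (camera adjusted p = 2.06e-05, and 0.127 with an estimated correlation). Krt10 reached 167 ± 20.4 CPM and was at least 334-fold higher, Krtdap at least 69.6-fold higher, and Krt1 had 2 counts against 1614 and 850, a ratio of 924 with a 95% counting interval from 256 to 7634. Calm4 had no counts in Lgr6-negative libraries but did not pass (adjusted p = 0.0617, from 2.66e-04 in DESeq2 to 0.139 over the alternatives, passing also in limma-voom at 0.0145, without a filter at 0.0302 and without replicate 1 of the Lgr6-positive population at 0.0408). Haemoglobin genes took 0.164% and 0.133% of the counts of the Lgr6-positive libraries and 0.00150% and 0.00152% of those of the Lgr6-negative libraries. Of 7 tested erythroid genes, the 6 globins were higher, also when adjusted over the list alone, and Alas2 did not pass (camera adjusted p = 1.47e-05, and 0.127 with an estimated correlation). Hbb-b1 was at 589.6 ± 108 against 9.87 ± 6.90 CPM (log2 fold change 5.90, SE 0.64), Hba-a1 was higher by 6.04 (SE 0.75) and Hba-a2 at least 164-fold, or 79.2-fold without replicate 1 of the Lgr6-positive population. Globin copies share reads, and Hbb-b2 (6.61, SE 1.197) and Hbb-bt held identical counts in 4 of 4 libraries, so single copies are uncertain. The number of higher globins and the list test therefore took the same values more than once. These genes, too, moved opposite to the immune list, with its median of -3.87.

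Nerve and muscle genes did not pass the test, which called hardly any simulated genes changed 2-fold or 4-fold. None of 6 Schwann cell genes passed in edgeR, also when adjusted over the list alone, nor in DESeq2 or limma-voom, though 3 had an unadjusted p under 0.05. Among the 6 were Mbp (log2 fold change -1.81, adjusted p = 0.0884), L1cam (-2.38, 0.187), Erbb3 (3.04, 0.191) and Ncam1 (3.10, 0.419). L1cam was at -1.02 without replicate 1 of the Lgr6-negative population, and Ncam1 at 1.26 without replicate 2 of the Lgr6-positive population. The camera adjusted p was 0.735, and 0.851 with an estimated correlation, and the direction in camera was down while the median was 0.38, or -1.19 without replicate 2 of the Lgr6-positive population. Erbb3 passed without replicate 1 of the Lgr6-negative population (log2 fold change 6.95, adjusted p = 9.55e-04, the lowest in a range up to 0.329), with the replicate block (4.33, 0.0430) and without a filter (0.0287). The 2 tested skeletal muscle genes, Ttn (adjusted p = 0.694) and Ckm (0.845, with counts in 1 library of each population), did not pass, 0 passed when adjusted over the list alone, and so few genes were not tested as a list.

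In the Wnt pathway list, 4 of 16 tested genes were higher and 12 did not pass, 5 were higher and 1 lower when adjusted over the list alone, and the list did not stand apart (camera adjusted p = 0.138, and 0.323 with an estimated correlation). The higher genes were Lgr4, the cyclin gene Ccnd1 (log2 fold change 3.50, SE 0.62), of which other genes cover 23.4% of the exonic bases, and the ligand genes Wnt4 (7.41, SE 1.52) and Wnt5a. Wnt5a had no counts in Lgr6-negative and 108 ± 10.2 CPM in Lgr6-positive libraries, at least 215-fold higher. Wnt4 had 0 and 6 counts in the Lgr6-negative libraries, so its ratio rests on replicate 2 of that population. In the Notch pathway list, 2 of 13 were higher, 1 was lower and 10 did not pass, with 5 higher and 1 lower when adjusted over the list alone. Notch1 rose to 379.8 ± 167 from 50.5 ± 4.75 CPM (2.91, SE 0.50) and the target gene Hey1 by 4.15 on the log2 scale (SE 0.85), whereas Notch2 fell by 2.37 on the log2 scale (SE 0.45). Notch3 did not pass (5.32, SE 1.42, adjusted p = 0.0505), but passed under 11 of 14 alternatives, in a range from 3.48e-06 to 0.0534. These included the fits without any 1 of the 4 libraries, in which the lone library was assumed to vary like the other group. The others were the replicate block (0.00517), DESeq2 (3.53e-04), limma-voom (0.0427), DESeq2 size factors (0.0394), library size only (0.0408), no filter (2.94e-05) and no Rn45s (0.0461). The log2 fold change of Notch3 was 9.29 without replicate 2 of the Lgr6-negative population, which left 1 count in that population. The Notch list passed camera (adjusted p = 0.0128, and 0.188 with an estimated correlation), but not without replicate 1 of the Lgr6-positive (0.0530) or of the Lgr6-negative population (0.0797). Hey1 lost its call without replicate 1 of the Lgr6-positive population (adjusted p = 0.116) and in limma-voom (0.118), in a range from 8.05e-07.

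Genes proposed to mark mammary stem or progenitor cells went both ways: 3 of 15 were higher, 2 were lower and 10 did not pass, with 4 higher and 2 lower when adjusted over the list alone. Tspan8 was at least 77.3-fold higher, Sox9 rose by 3.78 on the log2 scale (SE 0.84) and Sox10 by 4.92, the last named after its value was seen. Cd44, an adhesion receptor that leukocytes also carry, was at 345 ± 69.8 against 2155 ± 35.5 CPM (log2 fold change -2.64, SE 0.28), and Inpp5d, a phosphatase gene of blood cells, was lower by -3.22 (SE 0.73). Without replicate 2 of the Lgr6-negative population, the log2 fold change of Sox9 was 5.70. Camera gave an adjusted p of 0.262 (0.420 with an estimated correlation) and fry 0.0245. Inpp5d lost its call without replicate 1 of the Lgr6-negative population (0.107) and under library-size scaling (0.0605), in a range from 2.37e-04. Sox10 lost its call without replicate 2 of the Lgr6-positive (0.0512) or of the Lgr6-negative population (0.116), under the stricter filter (0.05003) and in limma-voom (0.0512), in a range from 4.70e-05.

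In the list of EGF receptors and their ligands, only Erbb2 of 10 tested genes was higher in edgeR, at 141 ± 41.3 against 3.90 ± 5.29 CPM (log2 fold change 5.18, SE 1.37, adjusted p = 0.0496), and 7 were higher and 1 lower when adjusted over the list alone. In DESeq2, 7 were higher and 1 lower, and in limma-voom 4 were higher and 1 lower. The list ranked above other genes in camera (adjusted p = 0.00169, and 0.143 with an estimated correlation). Egfr (4.74, SE 1.34, adjusted p = 0.0617) and Areg (2.47, SE 0.71, 0.0643) did not pass, nor did the neuregulin gene Nrg1 (0.0898), which had no counts in Lgr6-positive and 79 and 30 counts in Lgr6-negative libraries. Egfr passed without either Lgr6-positive library (0.00462 and 0.0350) and without replicate 1 of the Lgr6-negative population (7.89, 3.98e-04), which left 2 counts. It also passed with the replicate block (0.0123), in DESeq2 (7.80e-04) and limma-voom (0.0495), with DESeq2 size factors (0.0491) and without a filter (8.04e-04), in a range up to 0.0673. Erbb2 missed the threshold under the stricter filter (0.0521) and without ribosomal protein and haemoglobin genes (0.0512), in a range from 1.93e-06. Without replicate 2 of the Lgr6-negative population, which left 1 count, Erbb2 was at 9.66. Areg passed under library-size scaling (0.0378), without a filter (0.0391) and in DESeq2 (0.00450, in a range up to 0.184), and Nrg1 in DESeq2 (0.00780) and limma-voom (0.0315, in a range up to 0.472). Of 16 basement membrane genes, 6 were higher and 10 did not pass, with 8 higher when adjusted over the list alone (camera adjusted p = 1.06e-04, and 0.127 with an estimated correlation). Hspg2, the perlecan gene, reached 406 ± 50.3 against 28.1 ± 10.3 CPM (3.85, SE 0.51), Col4a6 was at least 143-fold higher, or 54.4-fold without replicate 2 of the Lgr6-positive population, and Lamc1 (2.24, SE 0.49) and Nid1 (2.72, SE 0.66) rose. Without replicate 2 of the Lgr6-negative population, Lamc1 (0.0745) and Nid1 (0.105) did not pass, in ranges from 0.00289 and 0.00253. The immune list, at a median of -3.87, moved opposite to both lists.

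None of 26 proliferation genes passed in edgeR's test, over all genes or when adjusted over the list alone, and none passed in DESeq2 or limma-voom; 1 had an unadjusted p under 0.05. Their median log2 fold change was -0.14, or 0.25 under library-size scaling and 0.03 without replicate 1 of the Lgr6-positive population (camera adjusted p = 0.634, and 0.777 with an estimated correlation). In the simulated data, 0 of 67 genes changed 2-fold and 1 of 67 changed 4-fold were called. Changes of that size in single proliferation genes could thus have been missed. Pcna (-1.33, SE 0.55, adjusted p = 0.172), Cenpf (1.57, SE 0.87), Mcm5 (-2.06, SE 1.29) and Birc5 (-3.05, SE 2.32) had the smallest p-values of the list. The last 3 depended on single libraries. Without replicate 1 or 2 of the Lgr6-negative population Cenpf was at 0.97 or 2.52, without replicate 1 Mcm5 was at -1.34, and Birc5 had 15 and 0 counts in the Lgr6-positive libraries, so without the first no ratio can be given for it. Immediate early and stress genes went both ways, with 3 of 20 higher, 5 lower and 12 not passing, and 3 higher and 7 lower when adjusted over the list alone (camera adjusted p = 0.457, and 0.734 with an estimated correlation). Egr1 rose to 3562 ± 178 from 728 ± 193 CPM (2.29, SE 0.26), while Nr4a1 (-2.21, SE 0.31) and the phosphatase gene Dusp1 (-1.68, SE 0.25) were lower. Zfp36 (-0.89, SE 0.18) was lower too but not under library-size scaling (0.166) or in DESeq2 (0.325), in a range from 9.81e-04. The others past the threshold, named after their values were seen, were Fos (1.09), Fosb (1.25), Hspa1a (-1.23) and Hsp90aa1 (-1.23). Each of these 4 missed it in DESeq2 (adjusted p 0.133 to 0.180), Fos (0.0722) and Fosb (0.0527) without replicate 2 of the Lgr6-positive and Hspa1a (0.146) without replicate 2 of the Lgr6-negative population. Under library-size scaling Hspa1a (0.159) and Hsp90aa1 (0.141) missed it too, and Hspa1a also with DESeq2 size factors (0.0520) and the stricter filter (0.0506). The lowest adjusted p over the alternatives was 9.00e-04 for Fos, 1.57e-04 for Fosb, 0.0132 for Hspa1a and 0.00544 for Hsp90aa1. The median of the list was -0.10, against 0.34 under library-size scaling and 0.10 without replicate 1 of the Lgr6-positive population.

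Over the 19 lists tested, camera called 12 higher and 1 lower with its preset correlation and 0 with an estimated one, while fry called 13. Lists with a negative estimate, such as the immune (-0.023) and basal (-0.041) lists, lost their call too. With an estimated correlation, camera rests on the few residual degrees of freedom of 4 libraries. Where the estimate was negative, and thus below the preset 0.01, the estimated correlation cannot have removed the call. There the few degrees of freedom did. For lists with an estimate above 0.01, the 0 calls cannot tell correlation between genes from the small number of libraries. The PValue of fry tests whether a set's genes move, on balance, one way, and its PValue.Mixed whether they change in either direction.

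**Figure D3:**
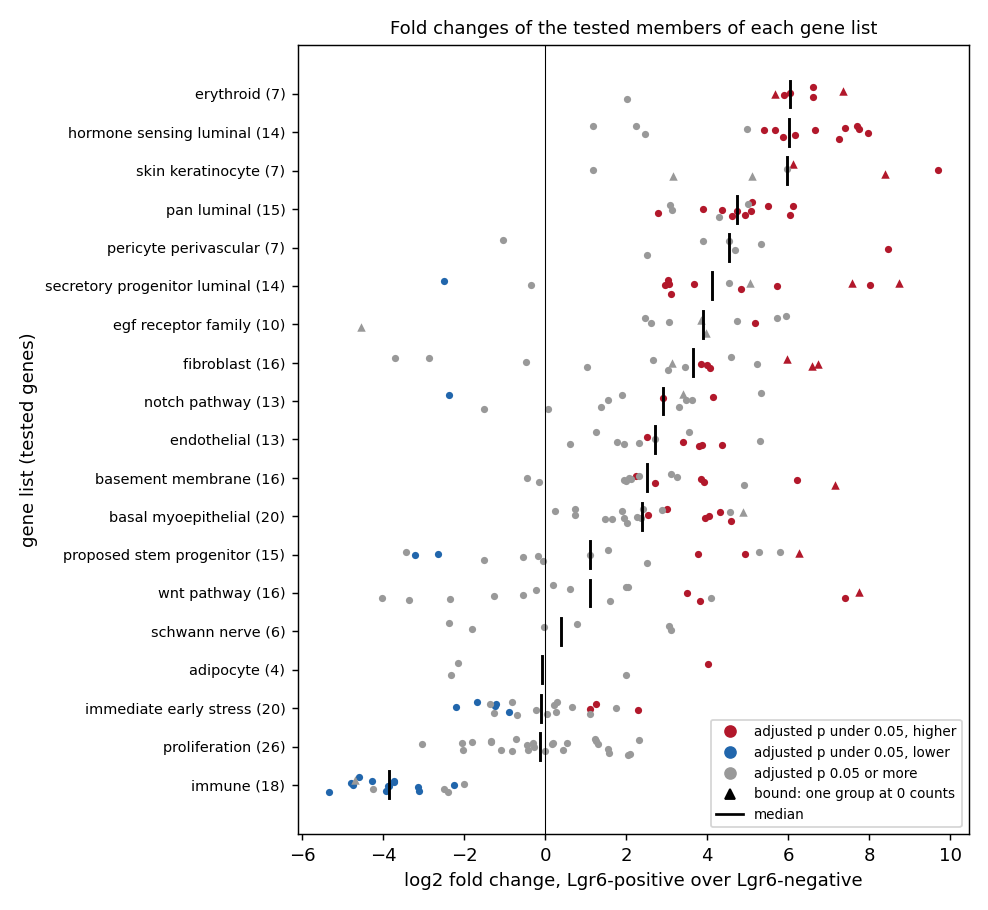
Log2 fold change (Lgr6-positive over Lgr6-negative) of each tested member of the 19 lists, with the number of tested genes in brackets, the median as a black bar, and triangles for genes without counts in 1 population, drawn at their bound. Immune genes have a median of -3.87 and hormone-sensing luminal genes one of 6.02, while proliferation genes scatter around -0.14.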

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

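The alternatives were fixed before the data were examined, except leaving out Rn45s and not rounding counts, which were chosen after seeing the data. Against 524 genes higher in Lgr6-positive cells, there were 967 without a filter, 298 with a stricter filter, 1566 in DESeq2 and 954 at an adjusted p under 0.1, and 678 to 956 in leave-one-out fits. Against 533 lower genes, there were 327 with library size only, 854 without a filter, 1025 in DESeq2 and 834 at an adjusted p under 0.1, and 540 to 1030 in leave-one-out fits. The stricter filter asked for at least 10 counts in at least 3 libraries, so it removed every gene without counts in both libraries of a population. Among the reported calls, 114 higher and 63 lower genes were of this kind and were not tested under it. Fewer or more genes tested also changes the adjustment under the filters. For the other alternatives the cause was not tested. Of the 1057 calls, between 678 (stricter filter) and 1057 (no filter, counts not rounded) were shared by an alternative, with 0 changes of sign. With the replicate block, 678 genes were higher and 662 lower. In leave-one-out fits the lone library was assumed to vary like the other group, so calls gained in them rest on that assumption.

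Lgr6, at 5.52 and not past the threshold, passed at 5.58 with DESeq2 size factors, 5.997 with library size only, 5.51 without a filter, 5.49 with the replicate block, 5.52 without Rn45s and 5.61 in DESeq2. It ran from 4.19 to 6.74 in leave-one-out fits. Lgr5 changed sign to 0.40 with the replicate block and 0.36 in limma-voom, and ran from -2.51 to 3.62 in leave-one-out fits, as did Ckm, from -7.03 to 5.96. The cause was not tested. With an estimated correlation, 0 lists were higher and 0 lower, against 12 and 1. The similarity gap between libraries of the same and of different populations moved from 0.329 to 0.269 with the stricter filter. Of 1800 values of 132 genes, 1711 kept direction and side of the threshold, 45 lost the call, 39 gained one and 5 changed sign. Of 302 list values, 282 kept theirs, 18 lost the call and 2 gained one. Depth limits what can be called near the floor of 3 counts.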

Other observations

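The 12 lists in this part were written after values were seen. Some hold genes already named among the leading ones, such as Treml4, Scd1 and Btn1a1. Their p-values are thus no independent support. Monocyte genes were lower in Lgr6-positive cells in 9 of 10 cases, with 1 not passing and 10 lower when adjusted over the list alone (camera adjusted p = 6.72e-08, and 0.176 with an estimated correlation). They included the chemokine receptor gene Ccr2 (log2 fold change -5.05), Spn (-6.52) and Cd300e, which was at least 144-fold lower. Ly6c2 was at -6.84, or -10.17 to -5.92 over the alternatives, with 3 and 57 counts in the Lgr6-positive libraries. Natural killer cell genes were lower in 7 of 10 cases, with 3 not passing and 10 lower when adjusted over the list alone (2.37e-10, and 0.176 with an estimated correlation). Nkg7 was at least 349.8-fold lower, the granzyme gene Gzma had a count ratio of 1987 (95% counting interval 356 to 78523) and Ccl5 was at -7.18. Of 7 neutrophil genes, 4 were lower and 3 did not pass, with 1 higher and 5 lower when adjusted over the list alone (0.00859, and 0.176 with an estimated correlation). These 4 were S100a8 (-2.72), S100a9 (-2.90), Csf3r (-4.56) and Ngp (-4.06). Retnlg went the other way, with 79 and 149 counts in Lgr6-positive and none in Lgr6-negative libraries. It did not pass in edgeR (adjusted p = 0.0725), but passed in DESeq2 (8.92e-04), in limma-voom (0.0191) and without replicate 1 of the Lgr6-positive population (0.0368), in a range up to 0.204. Of 7 conventional dendritic cell genes, Ccr7 (-5.82), Irf8 (-4.24) and Irf4 (-5.16) were lower and 4 did not pass, with 5 lower when adjusted over the list alone (2.24e-05, and 0.176 with an estimated correlation). Of 6 plasmacytoid dendritic cell genes only Irf7 was lower (-4.70, edgeR adjusted p = 0.0289, but 0.276 without replicate 1 of the Lgr6-negative population, 0.0560 with library size only and 0.104 in limma-voom, in a range from 2.91e-05), 5 did not pass, and 1 was higher and 2 lower when adjusted over the list alone (0.307, and 0.421 with an estimated correlation).

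None of 8 B cell genes passed in edgeR, also when adjusted over the list alone (camera adjusted p = 0.171, and 0.366 with an estimated correlation, with fry at 0.0400). None of 8 T cell genes passed either, with 4 lower when adjusted over the list alone (0.00318, and 0.176 with an estimated correlation, 0.143 with a stricter filter and 0.0638 without replicate 1 of the Lgr6-positive population). Neither of 2 tested mast cell genes passed, but Ms4a2 (74 and 3 counts), Cma1 (56 and 8) and Fcer1a (31 and 4), below the filter, had counts in Lgr6-negative libraries alone. The mast cell list, too short to test as reported, was lower in camera without a filter (adjusted p = 0.00328) and without replicate 2 of the Lgr6-negative population (0.00353), but not without replicate 1 (0.107) or 2 (0.102) of the Lgr6-positive population. Of 6 macrophage genes, Apoe was higher (1.80, edgeR adjusted p = 0.0449, but 0.102 without replicate 1 of the Lgr6-negative population, in a range from 0.00104), also when adjusted over the list alone, and 5 did not pass, among them Mrc1 (1.91, or 0.58 to 2.57 over the alternatives), C1qb (1.14, or 0.33 to 2.75) and Adgre1 (-2.49). Adgre1, the F4/80 antigen, had 227 and 3 counts in Lgr6-positive against 375 and 565 in Lgr6-negative libraries and was lower without replicate 1 of the Lgr6-positive population, which left 3 counts (-7.64, adjusted p = 4.10e-04, in a range up to 0.528). The macrophage list had a camera adjusted p of 0.0862 (0.421 with an estimated correlation), but 0.0371 without replicate 1 of the Lgr6-negative population and 0.0348 without a filter, in a range up to 0.512. Of 11 fatty acid synthesis genes, Scd1, Elovl6 (7.11), Me1 (4.85) and Srebf1 (2.91) were higher and 7 did not pass, with 6 higher when adjusted over the list alone (0.00313, and 0.176 with an estimated correlation). Me1 missed the threshold in limma-voom (adjusted p = 0.122, in a range from 1.41e-07), and Srebf1 without replicate 1 of the Lgr6-positive (0.0521) or of the Lgr6-negative population (0.130), with a stricter filter (0.05008) and in limma-voom (0.0572), in a range from 0.00206. Of 9 genes of the milk fat globule and fat uptake, 6 were higher and 3 did not pass. When adjusted over the list alone, 7 were higher (camera adjusted p = 0.00230, and 0.176 with an estimated correlation). Among the higher genes were Mfge8 (5.73, or 4.85 to 8.12 over the alternatives), Cd36 (2.19) and Muc15 (4.50). Without replicate 2 of the Lgr6-positive population, the list of fatty acid synthesis had a camera adjusted p of 0.0603 and that of milk fat 0.0549, in ranges from 2.78e-04 and 0.00129.

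Of the tests below, those of scaling, of leukocyte classes, of luminal against endothelial genes, of hormone-sensing against basal genes, of globin copies and of red cells were chosen after the result was seen. Of 18 tested immune genes, 13 were lower in Lgr6-positive libraries, and the list had a median of -3.87. The median closest to 0 over 3 other scalings was -3.42. These moved all log2 fold changes by a median of 0.03 (DESeq2 size factors), 0.45 (library size only) and -0.001 (without Rn45s). Shifts so small could not bring the list near 0, so this test cannot decide on scaling beyond these 3. After a linear trend on gene length and GC content was removed, the median was -3.47 (95% bootstrap interval -3.99 to -2.79). That argues against length and GC content as the whole cause. The macrophage median lay 7.64 above the monocyte median (exact permutation over 6 and 10 genes, p = 0.00375). Both lists were written after values were seen, and genes are not independent replicates. Only Apoe of the macrophage list passed, and the camera adjusted p of that list was 0.0862. Adgre1, a member of the list, was at -2.49, and at -7.64 without replicate 1 of the Lgr6-positive population. The immune list, with the macrophage markers Cd68 and Csf1r among its 18 tested genes, held no positive fold change. Whether all leukocyte classes had a lower share alike is thus not decided. The markers of the lineage depletion are not given and Ptprc was at 1466 CPM in Lgr6-negative libraries, so a depletion that differed between classes or populations may have contributed and stays open, as does a biological difference between the populations, which was not tested.

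Of the tested genes, 11 of 15 pan-luminal, 6 of 20 basal, 5 of 13 endothelial and 6 of 16 fibroblast genes were higher in Lgr6-positive libraries. If fewer leukocytes raised every other cell type alike, luminal and endothelial genes should rise by the same amount, but the luminal median was higher by 2.02 (permutation over genes, p = 0.00112), more than the SD of the genes of either list (1.01 and 1.32). This deciding rule was set after the result was known, and under an earlier one, which asked for similar starting levels in Lgr6-negative libraries (16.6 CPM in endothelial and 7.18 CPM in luminal genes), the test stayed undecided. Some endothelial genes, such as Pecam1, are also made by leukocytes, which would lower their fold. Hormone-sensing luminal genes were above basal genes by 3.63 (SD 2.21 and 1.38, permutation over genes, p = 8.00e-05). That pair was chosen after the medians were seen and holds the highest and the lowest of the epithelial lists (6.02 and 2.39). The rises thus differed between these lists, though the basal and endothelial medians were close, at 2.39 and 2.71. Genes are not independent replicates, and the rule and the second pair were set after values were known. Neither comparison therefore decides whether an equal rise was the whole cause. A smaller part shared by all types, unequal recovery of the types in the sort, and a biological difference between the populations, which was not tested, stay open too.

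Haemoglobin genes were higher in Lgr6-positive libraries. Reads shared between near-identical copies are argued against, since the lowest Lgr6-positive share of all haemoglobin genes was 87.1 times the highest Lgr6-negative share. Red cells in the Lgr6-positive pool may be a source, although red cells were lysed; whether the lineage depletion covered them is not given. Of 9 other red-cell genes, 0 passed in edgeR, also when adjusted over the list alone, with a median log2 fold change of 0.35 (95% bootstrap interval -1.21 to 2.02), a mean of 0.03 and a camera direction of down (adjusted p = 0.971, and 0.973 with an estimated correlation). Most lie near the floor or are widely expressed, so this cannot be told apart from expression in the sorted cells.

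For the 1057 genes past the threshold, the 4 libraries allow 3 splits into 2 and 2, too few for a share under 0.05. The real split, 1 of the 3, gave 1057 genes and the highest of the others 0.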
